A study of Homo sapiens with 35 samples.

How the data were processed

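Total RNA of HCT116 cells was prepared with a spin column kit (RNeasy) and hybridised to Affymetrix whole-transcript gene arrays, 1 sample per array, per the labels' protocols and the series' design text. Cells grew in McCoy's 5A medium with fetal calf serum. The deposited values, 1 per transcript cluster and array, are on the log2 scale, which was judged from their range and shared floor. They were made by the authors with Partek, per the submitters' processing notes, which give no version. The design text names a one-way analysis of variance in the same software as the authors' test. The background correction, summarization and normalization behind the log2 values, and the origin of the floor, are not given in the sources used here. The highest and lowest values were the same on all arrays. A floor shortens the fold of dim genes, and a normalization to one shared distribution can hide a change that moves most genes one way, so changes are relative to the other genes.
The 35 arrays were grouped by their titles into 14 groups with 2 or 3 replicates each. The unit of the 5-fluorouracil concentration could not be checked, so the concentration is not used here. No array of normoxic cells from the hypoxia experiment and no array of a knockdown line in DMSO or high glucose medium was analysed here. One hairpin line represented each target, so an effect of the hairpin on its target cannot be told apart from other properties of that line. No pair of arrays held identical values (0 identical pairs). No batch, scan date or culture was given in the labels.
Of the 32321 transcript clusters, 19158 had 1 gene symbol in the platform annotation, 1388 had several and 11775 had none listed. Symbols were looked up through Entrez identifiers in the supplied gene table, which changed 0 of them. For the 637 genes with over 1 cluster, the cluster with the highest mean over all arrays was kept, which left 18404 genes to test. CDK8 shares its only cluster with ADRA1B and is therefore outside this set, and its values come from a fit of every cluster. At the floor on all 35 arrays lay 1491 clusters and 112 genes, which stayed in the main test. A gene at the floor on every array of a group has only a bound there, and no gene's change was given from such a group.
Knockdown lines were compared with shControl cells, and with each other, within each experiment with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 mean per group and all arrays of the experiment sharing the estimate of the spread. The comparisons of 5-fluorouracil with DMSO and of low with high glucose used the same fits. Hypoxic shControl cells, and the difference between a knockdown's effect under stress and in normal growth, were tested in 1 fit of all 35 arrays. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05, and are two-sided. Values were read with the data.table package (version 1.17.8).
In total 24 gene lists with 714 genes, of which 648 had a tested row, were written before the data were examined. They cover the kinase module and the core of Mediator, hypoxia targets, glycolysis, ATF4 targets, endoplasmic reticulum chaperones, sterol and fatty acid synthesis, beta-catenin targets, immediate early genes, interferon-stimulated genes, S phase, mitosis, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, histones, NF-kB, TGF-beta with epithelial-mesenchymal transition, differentiated colon epithelium, and markers of fibroblasts, leukocytes and endothelium. Of the 13 mitochondrially encoded genes 0 had a tested row, so 23 lists were tested, each against all other genes with camera, with a preset correlation of 0.01 between genes and again with a correlation estimated from the residuals, adjusted over the lists of a comparison. Members were also adjusted over the list alone. Of the lists tested, 1 is not reported here, although it counts among the lists called.
The genes named in the text followed a rule set beforehand: the targets CDK8 and CDK19, then up to 10 higher and 10 lower genes per comparison with the largest absolute change among those past the threshold whose replicate values did not overlap, up to 4 members per list with the largest change past the threshold or otherwise the 2 with the smallest p, and up to 5 in each direction for direct comparisons and differences of effects. TXNIP and ARRDC4 in the glucose experiment, CDKN1A and MDM2 in the 5FU experiment and VEGFA and NDRG1 in the hypoxia experiment were to be named whatever their values. The text gives fewer genes than the rule allows, taken from the top.
Genes induced by a stress were those past the threshold and at least 2-fold higher in stressed shControl cells, and their medians in the knockdown lines were set beside 100 simulated data sets with no knockdown effect. The correlation of the knockdown effects was set beside simulated unchanged groups that share controls.
The alternatives tried were another quantile normalization, subtraction of each array's median, leaving out the 40% dimmest genes, testing every cluster, fitting all 35 arrays or only the groups compared, the replicate number as a block, eBayes with trend and robust options, the unmoderated one-way analysis of variance named in the design text, shControl cells in high glucose or DMSO as the comparator of hypoxic cells, and leaving out each array in turn. Each fitting step was first tested on simulated data with 200 changed genes among 18404. The changed genes were drawn from those with a mean over 2 log2 units above the floor, and each gene's noise was drawn independently. The shares recovered therefore do not cover dim genes or deviations shared by all genes of an array. For shCDK8 against shControl cells in normal growth, 61.2%, 89.6% and 98.5% of genes changed 1.5-, 2- and 4-fold were recovered. The shares were 41.8%, 77.6% and 97.0% for the 5FU experiment, 85.1%, 100% and 100% for low glucose, and 2.99%, 41.8% and 71.2% for hypoxia, the comparison with the least precision. For hypoxic against normally grown shControl cells they were 73.1%, 95.5% and 100%, and for the difference of the shCDK8 effect between hypoxia and normal growth 55.2%, 79.1% and 100%.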

Results

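Gene expression was measured in HCT116 cells, an established human colorectal carcinoma line with an activating mutation in CTNNB1. The cells carried a non-target short hairpin RNA (shControl), a hairpin against CDK8 (shCDK8) or a hairpin against CDK19 (shCDK19). CDK8 and CDK19 are paralogous kinases, either of which can occupy the kinase module of Mediator, the coactivator complex that links transcription factors to RNA polymerase II. The 35 arrays fell into 14 groups in 4 experiments. In the normal growth experiment each line had 3 arrays. In the 5FU experiment the shControl line had 2 arrays after DMSO and 2 after 12 h of 5-fluorouracil, an antimetabolite that inhibits thymidylate synthase, and each knockdown line had 2 arrays after 5-fluorouracil. In the glucose experiment the shControl line had 3 arrays in high and 3 in low glucose medium after 24 h, and each knockdown line had 3 in low glucose. In the hypoxia experiment each line had 2 arrays after 24 h at 1% oxygen. The deposited log2 values ended at a floor (20 before the logarithm), which held between 8.48% and 9.97% of the rows of an array. The 75th percentile lay between 8.96 and 9.25, and arrays of a group correlated with r between 0.980 and 0.999 across rows. The number of arrays limits the precision. Since no label says that replicates came from separate cultures, p-values measure only the spread between these arrays, which may be technical. Values are log2 fold changes ± SE from limma, and counts are genes at an adjusted p under 0.05 of 18404 tested. For the gene lists, fixed before the data were examined, counts of measured members are followed in square brackets by the counts adjusted over the list alone, and the p-values are adjusted ones from camera, which compares a list with all other genes. Where a list was called only with the preset correlation of 0.01 between genes, its p with an estimated correlation follows. Genes named as highest or lowest had replicate values that did not overlap between the groups compared.
The targeted transcripts were compared first. The CDK8 signal came from a transcript cluster that lists CDK8 together with ADRA1B, an adrenergic receptor gene, so it is given for that cluster. It was 4.35-fold lower in the shCDK8 line in normal growth (-2.12 ± 0.24, 3 arrays per group), 6.7-fold lower under 5-fluorouracil (-2.74 ± 0.16, 2 per group), 4.38-fold lower in low glucose (-2.13 ± 0.11, 3 per group) and 4.07-fold lower under hypoxia (-2.02 ± 0.20, 2 per group). The adjusted p-values were 0.00164, 0.0115, 5.31e-06 and 0.0347. In the shCDK19 line this cluster did not pass the test in any of the 4 experiments, with changes of 0.058 ± 0.24, -0.066 ± 0.16, 0.063 ± 0.11 and 0.63 ± 0.20 in the same order. CDK19 was 2.83-fold lower in the shCDK19 line in normal growth (-1.50 ± 0.11), 2.11-fold lower under 5-fluorouracil (-1.08 ± 0.088) and 2.95-fold lower in low glucose (-1.56 ± 0.087). Under hypoxia its change of -1.10 ± 0.14 missed the threshold (adjusted p = 0.0948). In the shCDK8 line CDK19 did not pass the test, with 0.33 ± 0.11 in normal growth (adjusted p = 0.0778), 0.15 ± 0.088 under 5-fluorouracil, -0.014 ± 0.087 in low glucose and 0.49 ± 0.14 under hypoxia (adjusted p = 0.113). Within the shControl line, CDK19 fell by 0.82 ± 0.09 on the log2 scale after 5-fluorouracil (adjusted p = 0.00726) and rose in low glucose (0.41 ± 0.087, adjusted p = 0.0051).

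**Figure D1:**
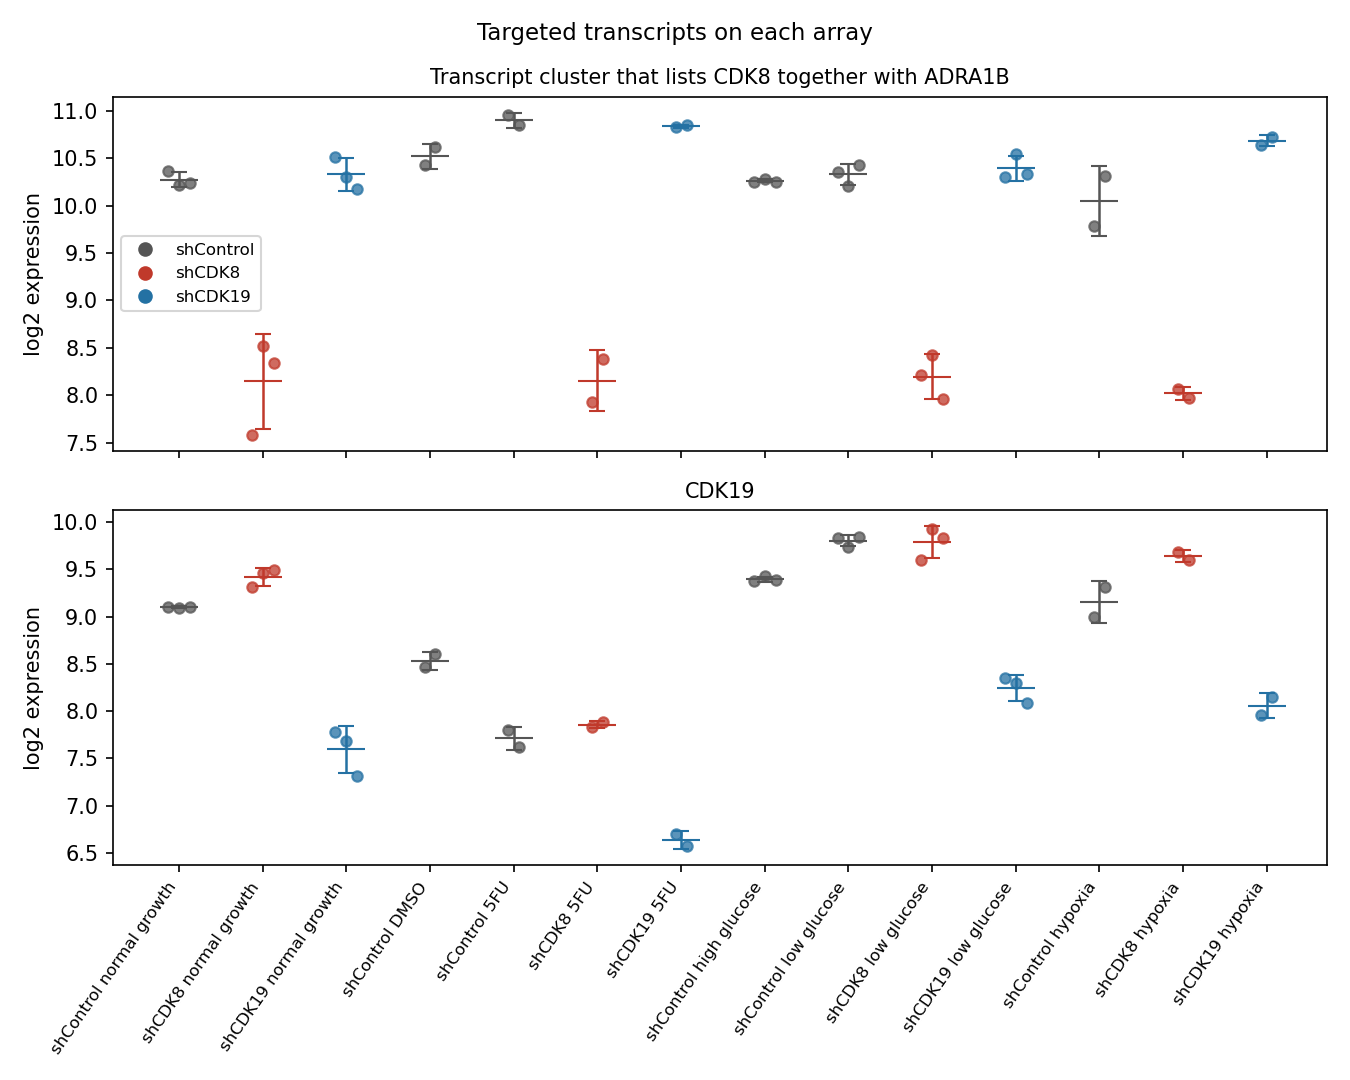
Log2 expression of the transcript cluster that lists CDK8 with ADRA1B (top) and of CDK19 (bottom) on each of the 35 arrays, by group. Points are arrays, horizontal bars are group means and vertical bars are SDs. The shCDK8 arrays lie below all other arrays for the CDK8 cluster, and the shCDK19 arrays lie below the other lines' arrays of the same experiment for CDK19.

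In normal growth TNFSF18, the ligand of the immune receptor GITR, was 68.0-fold higher in the shCDK8 line than in shControl cells (6.09 ± 0.15), the lysozyme gene LYZ 43.4-fold (5.44 ± 0.11) and the membrane protein gene TM4SF18 37.4-fold (5.23 ± 0.11). The calcium sensor gene VSNL1 (5.12 ± 0.066), TNFSF4, which encodes the OX40 ligand (4.40 ± 0.14), the guidance semaphorin SEMA3A (4.34 ± 0.062) and the epithelial ETS factor EHF (4.14 ± 0.13) followed. The cytidine deaminase APOBEC3G (3.74 ± 0.20) and the matricellular gene SPARC (3.71 ± 0.18) were higher as well. LYZ is also on the list of leukocyte markers, of which 2 of 14 were higher [2] and 1 lower [1] (adjusted p = 0.566). Genes at the other end were CYB5A, encoding cytochrome b5 (-4.08 ± 0.14, 16.9-fold lower), the glutamine transporter SLC38A5 (-3.29 ± 0.10), PRAF2 (-2.91 ± 0.088), the transcription factor MEF2C (-2.89 ± 0.11) and the polarity scaffold MPP7 (-2.88 ± 0.11). They were followed by SPTSSB, a subunit of serine palmitoyltransferase (-2.87 ± 0.070), the nuclear factor NFIB (-2.79 ± 0.057), the clathrin adaptor AP1M2 (-2.78 ± 0.081) and the dipeptidyl peptidase DPP4 (-2.56 ± 0.10). In all, 2091 genes were higher and 2488 lower, of which 207 and 122 changed at least 2-fold.
Genes of DNA replication and of mitosis were lower in the shCDK8 line. Of the S phase and E2F target genes, 37 of 44 were lower [39], with a median of -0.56, led by the primase subunit PRIM1 (-1.34 ± 0.12), the replicative helicase subunit MCM2 (2.01-fold lower) and POLE2 (-0.97 ± 0.14). The list's test gave p = 7.40e-17, and p = 0.278 with an estimated correlation. Of the mitosis genes, 1 of 44 was higher [1] and 26 lower [32], among them the phosphatase CDC25C (-1.24 ± 0.11) and HMMR (-1.05 ± 0.15; p = 1.86e-09, and p = 0.554 with an estimated correlation). Of the replication-dependent histone genes, 15 of 28 were lower [15] (p = 2.46e-05, and p = 0.0858 with an estimated correlation), with H4C4 (-0.87 ± 0.18) lowest. Of the targets of ATF4, the transcription factor of the amino acid response, 25 of 34 were lower [28], among them CHAC1, a glutathione-degrading enzyme (-1.65 ± 0.12), DDIT3 (-1.11 ± 0.12) and TRIB3 (-1.10 ± 0.098; p = 7.05e-12, and p = 0.0858 with an estimated correlation).
Lists higher in the shCDK8 line in normal growth included genes of NF-kB, of beta-catenin and of TGF-beta signalling and epithelial-mesenchymal transition. Of the TGF-beta and transition genes, 16 of 28 were higher [17] and 4 lower [4]. They included TGFB2 (3.63 ± 0.076), PMEPA1 (2.95 ± 0.19) and SNAI2, a repressor of epithelial genes (2.21 ± 0.11), while CDH1, which encodes E-cadherin, was lower (-1.70 ± 0.074; p = 6.07e-06, and p = 0.0858 with an estimated correlation). NF-kB and chemokine genes (8 of 26 were higher [9]; p = 9.88e-05, and p = 0.183 with an estimated correlation) included the inhibitor NFKBIA (0.97 ± 0.057). Of the beta-catenin and TCF targets, 12 of 26 were higher [12] and 3 lower [3], with BMP4 (1.59 ± 0.051) and AXIN2, a feedback inhibitor of Wnt signalling (1.48 ± 0.072), highest (p = 0.000141, and p = 0.0858 with an estimated correlation). Of the oxidative phosphorylation genes, 17 of 38 were lower [18], with UQCRH lowest (-0.70 ± 0.072; p = 7.70e-05, and p = 0.587 with an estimated correlation). Of the interferon-stimulated genes, 12 of 43 were higher [13] and 2 lower [2] (p = 0.00616, and p = 0.0858 with an estimated correlation). Core Mediator subunits were lower as a list (2 of 24 were higher [2] and 6 lower [8]; p = 0.0345, and p = 0.637 with an estimated correlation). Sterol and fatty acid synthesis genes were lower too (2 of 26 were higher [3] and 11 lower [12]; p = 0.0345, and p = 0.706 with an estimated correlation), with the squalene epoxidase SQLE at -1.14 ± 0.14. None of the 12 list calls held with an estimated correlation, where 5 lists had an unadjusted p under 0.05.
The shCDK19 line in normal growth differed from shControl cells in 676 higher and 625 lower genes. VSNL1 was 38.8-fold higher (5.28 ± 0.066), followed by EHF (4.47 ± 0.13), the adhesion receptor ADGRF1 (3.32 ± 0.17), the growth factors FGF9 (3.28 ± 0.18) and TGFB2 (3.14 ± 0.076), CAPN6 (3.11 ± 0.088) and ZNF704 (2.35 ± 0.077). Besides CDK19, the lowest genes were the extracellular peroxidase PXDN (-2.55 ± 0.070), the AMP-activated kinase subunit PRKAA2 (-2.53 ± 0.11), CHAC1 (-1.90 ± 0.12) and KLF12 (-1.84 ± 0.13). ATF4 targets were lower as in the other line: 14 of 34 were lower [21], with DDIT3 at -1.45 ± 0.12 (p = 3.31e-12, and p = 0.212 with an estimated correlation). Of the chaperones and other endoplasmic reticulum genes of the unfolded protein response, 4 of 25 were lower [5 lower and 1 higher], such as HERPUD1 (-0.39 ± 0.062; p = 0.000813, and p = 0.349 with an estimated correlation). Of the kinase module genes, 3 of 6 were lower [3 lower and 1 higher], namely CDK19 itself, MED13L (-0.52 ± 0.040) and MED13 (-0.21 ± 0.047), a list that holds the hairpin's target (p = 0.00724, and p = 0.469 with an estimated correlation).
Of the immediate early genes, which mark growth factor signalling, 4 of 37 were higher [6] and 11 lower [17] in the shCDK19 line, with DUSP1 at -0.64 ± 0.096 (p = 0.00162, and p = 0.245 with an estimated correlation). Genes of differentiated colon epithelium had a median of 0.037 (4 of 23 were higher [6] and 1 lower [1]; p = 0.0211, and p = 0.469 with an estimated correlation), with CEACAM1 highest (0.64 ± 0.13). None of the 11 list calls held with an estimated correlation, where 3 lists had an unadjusted p under 0.05. The count of 1301 genes rested on all arrays: leaving out any 1 of the 6 shControl and shCDK19 arrays gave between 662 and 814.
Compared directly, the knockdown lines differed in normal growth in 2378 genes higher and 2427 lower in shCDK8 than in shCDK19 cells. TNFSF18 (5.21 ± 0.15), TM4SF18 (4.82 ± 0.11) and TNFSF4 (4.45 ± 0.14) were the genes with the highest difference, and CYB5A (-4.22 ± 0.14), the glutamate transporter SLC1A3 (-3.91 ± 0.091) and DPP4 (-3.61 ± 0.10) those with the lowest. CDK19 was higher in the shCDK8 line (1.83 ± 0.11). The S phase genes were lower in shCDK8 cells (2 of 44 were higher [2] and 34 lower [35]; p = 1.44e-12, and p = 0.417 with an estimated correlation). Without shCDK8 replicate 1, an array that stood apart from its group, 7349 genes passed in place of 4805.
In shControl cells 5-fluorouracil raised 1320 genes and lowered 789 against DMSO (2 arrays per group). The kinase gene PLK2 rose 6.92-fold (2.79 ± 0.13), the death receptor FAS 5.7-fold (2.51 ± 0.11) and TIGAR 4.18-fold (2.06 ± 0.13). The tumour suppressor serpin SERPINB5 (2.40 ± 0.14) and the glycosyltransferase GALNT5 (2.39 ± 0.13) also rose. The cell cycle inhibitor CDKN1A rose 2.7-fold (1.43 ± 0.063) and the ubiquitin ligase MDM2 2.05-fold (1.04 ± 0.085). Among replication-dependent histone genes, 22 of 28 were lower [24] (p = 1.07e-21, and p = 0.175 with an estimated correlation). H2BC14 (-3.58 ± 0.098), H2AC4 (-2.96 ± 0.17) and H2BC7 (-2.59 ± 0.10) were among the lowest of all genes. Mitosis genes fell too (1 of 44 was higher [2] and 26 lower [31]; p = 1.54e-16, and p = 0.253 with an estimated correlation), such as CENPE (-1.27 ± 0.10), PLK1 (-1.24 ± 0.063) and AURKA (-1.17 ± 0.080).
Immediate early genes rose (13 of 37 were higher [18]; p = 7.27e-09, and p = 0.231 with an estimated correlation), with the matricellular gene CCN1 at 2.38 ± 0.11 and JUN at 1.88 ± 0.19. Of the ribosome biogenesis genes, 14 of 34 were higher [18 higher and 1 lower] (p = 7.27e-09, and p = 0.231 with an estimated correlation). Of the sterol and fatty acid genes, 9 of 26 were lower [11 lower and 1 higher] (p = 0.000258, and p = 0.654 with an estimated correlation). CCNE2, which encodes cyclin E2, rose by 1.43 ± 0.095. None of the 10 list calls held with an estimated correlation, where 4 lists had an unadjusted p under 0.05. Without shControl 5FU replicate 1 or 2 the count of 2109 genes was 225 or 310. The split was 1558 higher and 563 lower with each array's median subtracted, 792 higher and 783 lower without DMSO replicate 1 and 1851 higher and 1612 lower with the interquartile range as a covariate.
Under 5-fluorouracil the shCDK8 line had 293 genes higher and 352 lower than shControl cells. TM4SF18 (4.96 ± 0.14), VSNL1 (4.19 ± 0.13), SEMA3A (3.68 ± 0.15), TNFSF4 (3.63 ± 0.11), EHF (2.77 ± 0.14) and PHLDB2 (2.54 ± 0.10) were highest. The lowest were CYP4F11, a fatty acid hydroxylase (-3.29 ± 0.19), SLC38A5 (-3.20 ± 0.10), NFIB (-2.68 ± 0.091), DPP4 (-2.56 ± 0.19), CYB5A (-2.44 ± 0.17) and the G protein regulator RGS2 (-2.42 ± 0.094). CDKN1A (0.25 ± 0.063, adjusted p = 0.108) and MDM2 (-0.22 ± 0.085, adjusted p = 0.265) did not pass. Mitosis genes were higher in this line: 8 of 44 were higher [22 higher and 1 lower], led by PLK1 (0.96 ± 0.063) and AURKA (0.92 ± 0.080; p = 2.57e-13, and p = 0.649 with an estimated correlation). Of the histone genes, 3 of 28 were higher [13], with H2BC14 at 1.39 ± 0.098 (p = 1.45e-08, and p = 0.649 with an estimated correlation). None of these 5 list calls held with an estimated correlation, where 1 list had an unadjusted p under 0.05. The count of 645 fell to 110 without shControl replicate 1, 88 without shControl replicate 2, 158 without shCDK8 replicate 1 and 132 without shCDK8 replicate 2.
The shCDK19 line under 5-fluorouracil had 106 genes higher and 48 lower than shControl cells. EHF (4.85 ± 0.14), VSNL1 (4.47 ± 0.13), ADGRF1 (2.71 ± 0.079), PHLDB2 (2.07 ± 0.10) and ZNF91 (1.84 ± 0.18) were highest, and the cofactor VGLL3 (-2.44 ± 0.093), DPP4 (-2.33 ± 0.19) and the growth factor PDGFC (-1.70 ± 0.13) lowest. CDKN1A was higher (0.57 ± 0.063, adjusted p = 0.0277) and MDM2 did not pass (0.13 ± 0.085, adjusted p = 0.628). Sterol and fatty acid genes were lower as a list: 2 of 26 were lower [11], among them HMGCS1, an early enzyme of sterol synthesis (-0.74 ± 0.090; p = 2.95e-08, and p = 0.631 with an estimated correlation). Beta-catenin targets were higher (2 of 26 were higher [7]; p = 8.83e-05, and p = 0.601 with an estimated correlation), with RNF43 at 1.43 ± 0.12. Of the ATF4 targets, 3 of 34 were higher [7] (p = 9.70e-05, and p = 0.631 with an estimated correlation), with asparagine synthetase ASNS at 0.80 ± 0.063. Mitosis genes had a median of -0.17 (0 of 44 passed by limma [0], with 2 higher and 13 lower at an unadjusted p under 0.05; p = 9.57e-06, and p = 0.631 with an estimated correlation). None of these 8 list calls held with an estimated correlation, where 1 list had an unadjusted p under 0.05. The count of 154 fell to 9, 5, 5 and 5 without shControl replicates 1 and 2 and shCDK19 replicates 1 and 2 in turn.
Directly compared under 5-fluorouracil, 409 genes were higher and 537 lower in the shCDK8 than in the shCDK19 line. TM4SF18 (5.00 ± 0.14) and TNFSF4 (3.44 ± 0.11) were highest and NFIB (-3.95 ± 0.091) and CYP4F11 (-3.13 ± 0.19) lowest. Mitosis genes were higher in shCDK8 cells (20 of 44 were higher [35]; p = 5.47e-19, and p = 0.436 with an estimated correlation). CDKN1A had a difference of -0.32 ± 0.063 (adjusted p = 0.0504) and MDM2 of -0.35 ± 0.085 (adjusted p = 0.0822). Without shCDK8 replicate 1 or 2, 158 or 115 genes passed, and without shCDK19 replicate 1 or 2, 46 or 40.
Low glucose raised 2559 and lowered 3179 genes in shControl cells against high glucose (3 arrays per group). The peptide hormone gene SPX rose 11.7-fold (3.55 ± 0.15), and the stress transcription factor DDIT3, also called CHOP, rose 6.96-fold (2.80 ± 0.060). LURAP1L (2.99 ± 0.058), the cytokine receptor subunit IL20RB (2.50 ± 0.077) and keratin KRT7 (2.16 ± 0.076) rose as well. The receptor gene GPR15 (-2.57 ± 0.14), osteopontin SPP1 (-2.34 ± 0.081) and the fatty acid elongase ELOVL3 (-1.88 ± 0.11) fell. The ATF4 targets rose nearly as a whole: 30 of 34 were higher [30], among them TRIB3 (1.66 ± 0.065), CHAC1 (1.62 ± 0.043) and SESN2 (1.40 ± 0.048; adjusted p = 1.92e-21). Endoplasmic reticulum chaperone genes rose with them (21 of 25 were higher [22]), such as SEL1L (1.24 ± 0.053) and DNAJC3 (1.21 ± 0.078; adjusted p = 9.88e-18). S phase genes fell (42 of 44 were lower [42]), with CCNE2 at -1.44 ± 0.11, MCM4 at -1.28 ± 0.061 and MCM6 at -1.16 ± 0.067 (adjusted p = 7.86e-25). Mitosis genes also fell (41 of 44 were lower [43]), such as HMMR (-0.98 ± 0.058) and MAD2L1 (-0.92 ± 0.078; p = 3.77e-22, and p = 0.0594 with an estimated correlation). TXNIP, a glucose-responsive arrestin gene, did not pass (-0.041 ± 0.086, adjusted p = 0.786), while its relative ARRDC4 fell 2.26-fold (-1.18 ± 0.12, adjusted p = 3.47e-05). Oxidative phosphorylation genes were lower as a list (1 of 38 was higher [1] and 15 lower [17]; p = 4.73e-05, and p = 0.115 with an estimated correlation). Beta-catenin targets such as AXIN2 (-0.92 ± 0.083) were lower too (2 of 26 were higher [2] and 12 lower [13]; p = 0.00293, and p = 0.11 with an estimated correlation). Ribosomal protein genes were higher as a list (10 of 32 were higher [10]; p = 0.00162, and p = 0.128 with an estimated correlation). With an estimated correlation 4 of the 12 list calls held, among them those of S phase, ATF4 and endoplasmic reticulum chaperone genes.
In low glucose the shCDK8 line had 2222 genes higher and 1885 lower than shControl cells. VSNL1 (5.28 ± 0.096, 38.8-fold), SEMA3A (4.66 ± 0.086), TM4SF18 (4.60 ± 0.13), TNFSF4 (4.25 ± 0.082), TNFSF18 (3.76 ± 0.11) and TM4SF1 (3.55 ± 0.062) were highest. CYP4F11 (-3.42 ± 0.085), DPP4 (-2.98 ± 0.090), SLC38A5 (-2.97 ± 0.071), SPTSSB (-2.86 ± 0.062) and PRAF2 (-2.78 ± 0.044) were lowest. Sterol and fatty acid synthesis genes were lower: 1 of 26 was higher [2] and 17 lower [17], with SQLE at -1.02 ± 0.034 and ELOVL6 at -0.83 ± 0.074 (adjusted p = 1.43e-09). Replication-dependent histone genes were lower as well (17 of 28 were lower [18]), such as H2BC7 (-0.99 ± 0.082; adjusted p = 5.60e-09), and these 2 of the 10 lists called held with an estimated correlation. ATF4 targets were lower (1 of 34 was higher [1] and 12 lower [13]; p = 3.30e-05, and p = 0.0852 with an estimated correlation), with ALDH1L2 at -0.86 ± 0.099. Mitosis genes were lower (16 of 44 were lower [16]; p = 0.00026, and p = 0.532 with an estimated correlation), with CDC25C at -0.76 ± 0.069. TGF-beta and transition genes were higher (13 of 28 were higher [15] and 3 lower [4]), among them SNAI2 (2.04 ± 0.092; p = 0.00162, and p = 0.0556 with an estimated correlation). TXNIP did not pass (0.045 ± 0.086, adjusted p = 0.799) and ARRDC4 was higher (0.43 ± 0.12, adjusted p = 0.0236).
The shCDK19 line in low glucose had 1677 genes higher and 1994 lower than shControl cells. VSNL1 was 55.7-fold higher (5.80 ± 0.096), EHF 11.1-fold (3.48 ± 0.061) and the iron-siderophore binding gene LCN2 11.1-fold (3.47 ± 0.088), followed by the kinase gene DCLK1 (3.23 ± 0.11) and TGFB2 (2.95 ± 0.084). Apart from CDK19, UTS2B (-2.85 ± 0.14), the nuclear receptor NR5A2 (-2.58 ± 0.099) and PXDN (-2.34 ± 0.11) were lowest. Of the sterol and fatty acid genes, 23 of 26 were lower [23], led by HMGCS1 (-0.87 ± 0.060) and the sterol sensor INSIG1 (-0.80 ± 0.043; adjusted p = 9.99e-16). Endoplasmic reticulum chaperone genes were lower too (1 of 25 was higher [1] and 15 lower [16]), such as CRELD2 (-0.84 ± 0.049) and SEL1L (-0.77 ± 0.053; adjusted p = 3.73e-07). S phase genes were higher (23 of 44 were higher [28] and 1 lower [1]), among them GINS2 (0.69 ± 0.069), MCM4 (0.67 ± 0.061) and MCM5 (0.65 ± 0.062; p = 4.63e-12, and p = 0.121 with an estimated correlation). Interferon-stimulated genes were higher (15 of 43 were higher [18] and 3 lower [3]), with IFIT1 at 0.98 ± 0.11 (p = 0.000742, and p = 0.121 with an estimated correlation). Of the 12 list calls, those of sterol and endoplasmic reticulum chaperone genes held with an estimated correlation. TXNIP (0.36 ± 0.086, adjusted p = 0.0158) and ARRDC4 (0.73 ± 0.12, adjusted p = 0.00161) were higher. Directly compared, 2709 genes were higher and 2069 lower in the shCDK8 line, with TNFSF4 (4.05 ± 0.082) and TM4SF18 (3.90 ± 0.13) highest and DPP4 (-3.59 ± 0.090) and SLC38A5 (-3.43 ± 0.071) lowest. S phase genes were lower in shCDK8 than in shCDK19 cells (2 of 44 were higher [2] and 36 lower [38]; p = 6.10e-14, and p = 0.0704 with an estimated correlation). Histone genes were lower too (16 of 28 were lower [16]; adjusted p = 4.28e-08).
Hypoxic shControl cells were set against shControl cells in normal growth, which came from another experiment, so hypoxia and experiment cannot be told apart. Targets of the hypoxia-inducible factor HIF1A were higher: 40 of 44 were higher [41], with a median of 1.35 (adjusted p = 4.93e-37). ANKRD37 was 10.2-fold higher (3.35 ± 0.12), the lipase inhibitor ANGPTL4 9.32-fold (3.22 ± 0.17), the glucose transporter SLC2A3 6.78-fold (2.76 ± 0.094) and hexokinase HK2 5.87-fold (2.55 ± 0.097). HILPDA (2.48 ± 0.13), which is on lipid droplets, and the sterol regulator INSIG2 (2.45 ± 0.16) were next. The angiogenic factor VEGFA (1.17 ± 0.068) and NDRG1 (1.89 ± 0.099) were higher. Glycolysis genes were higher (18 of 21 were higher [18] and 3 lower [3]), such as ALDOC (2.41 ± 0.13; adjusted p = 9.61e-13). Immediate early genes were higher too (23 of 37 were higher [23]), such as DUSP1 (2.06 ± 0.094; adjusted p = 1.43e-10). S phase genes were lower (42 of 44 were lower [42]), with CLSPN at -1.89 ± 0.19 (p = 2.19e-22, and p = 0.0722 with an estimated correlation). Ribosome biogenesis genes were lower as well (29 of 34 were lower [29]), with UTP15 at -1.92 ± 0.20 and UTP20 at -1.66 ± 0.13 (p = 1.45e-16, and p = 0.0879 with an estimated correlation). The lowest single genes were FAM111B (-2.08 ± 0.19), POGLUT1 (-1.99 ± 0.17) and CHRNA5 (-1.96 ± 0.15). In all, 3879 genes were higher and 4922 lower, against 2332 higher and 5349 lower with each array's median subtracted.
Lists with smaller shifts in this comparison included lower ATF4 targets (6 of 34 were higher [6] and 22 lower [22]; p = 0.000105, and p = 0.179 with an estimated correlation), although DDIT4 was higher (1.77 ± 0.12). Oxidative phosphorylation genes had a median of -0.093, which turned to 0.0078 after quantile normalization (1 of 38 was higher [1] and 16 lower [15]; p = 0.00716, and p = 0.451 with an estimated correlation). Genes of differentiated colon epithelium had a median of 0.23 (p = 0.0395 with the preset correlation only), and some markers of other cell types were higher too. Of the leukocyte markers, 6 of 14 were higher [6] (p = 0.00836, and p = 0.319 with an estimated correlation), led by CD68 (1.52 ± 0.071). Of the fibroblast markers, 5 of 12 were higher [5] (p = 0.037, and p = 0.401 with an estimated correlation). Of the endothelial markers, 2 of 10 were higher [2] and 1 lower [1] (adjusted p = 0.131). With an estimated correlation 3 of the 14 list calls held, those of hypoxia targets, glycolysis and immediate early genes. Hypoxic shControl replicate 1 stood apart from its partner; without it 4549 genes passed in place of 8801, with 1433 higher and 3116 lower. The majority of lower genes turned without its partner, replicate 2 (6419 higher and 5677 lower), and against the DMSO arrays of the 5-fluorouracil experiment (3602 higher and 3391 lower).
Under hypoxia the shCDK8 line had lower levels of hypoxia targets than shControl cells (2 arrays per group). Of these, 1 of 44 was higher [1] and 13 lower [20], with a median of -0.42 (p = 1.67e-08, and p = 0.495 with an estimated correlation). ANKRD37 was 5.47-fold lower (-2.45 ± 0.081), the peptide hormone ADM 2.92-fold (-1.55 ± 0.078), HILPDA 2.67-fold (-1.42 ± 0.23) and VEGFA 1.6-fold (-0.68 ± 0.097, adjusted p = 0.0273). NDRG1 did not pass (-0.53 ± 0.12, adjusted p = 0.0719). Sterol and fatty acid genes were lower (12 of 26 were lower [17]), with INSIG1 at -2.41 ± 0.072, STARD4 at -1.98 ± 0.20 and SQLE at -1.48 ± 0.14 (p = 1.67e-08, and p = 0.55 with an estimated correlation). Ribosome biogenesis genes were higher (5 of 34 were higher [15 higher and 1 lower]), such as UTP20 (1.53 ± 0.25) and RRS1 (1.34 ± 0.18; p = 4.45e-07, and p = 0.578 with an estimated correlation). Immediate early genes were lower as a list (5 of 37 were higher [8] and 15 lower [18]), with the phosphatase DUSP1 at -2.46 ± 0.085 and EGR1 at -1.57 ± 0.074 (p = 0.0047, and p = 0.402 with an estimated correlation).
Over all genes, 885 were higher and 458 lower in hypoxic shCDK8 cells, against 1076 higher and 1120 lower with each array's interquartile range as a covariate and 4076 higher and 4472 lower without shControl replicate 2. TNFSF18 (5.99 ± 0.10), VSNL1 (5.34 ± 0.12), SEMA3A (5.03 ± 0.15), LYZ (4.89 ± 0.12) and EHF (4.69 ± 0.23) were highest. CYB5A (-3.49 ± 0.21), SPTSSB (-3.05 ± 0.22), S100A14 (-2.90 ± 0.11), CYP4F11 (-2.74 ± 0.15) and RGS2 (-2.69 ± 0.097) were lowest. The markers of other cell types had negative medians, -0.24 for fibroblasts, -0.26 for leukocytes and -0.34 for endothelium, and did not pass (camera adjusted p = 0.103, 0.129 and 0.0764). None of the 10 list calls held with an estimated correlation, where 2 lists had an unadjusted p under 0.05. The count of 1343 was 8548 without shControl replicate 2, and 6 and 2 without shCDK8 replicates 1 and 2. The median of the hypoxia targets lay between -0.53 and -0.37 without any 1 of these 4 arrays. By limma 0 members passed without either shCDK8 array (18 and 18 were lower at an unadjusted p under 0.05). The number was 1 without either shCDK19 array, which enter only the shared estimate of the spread.

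**Figure D2:**
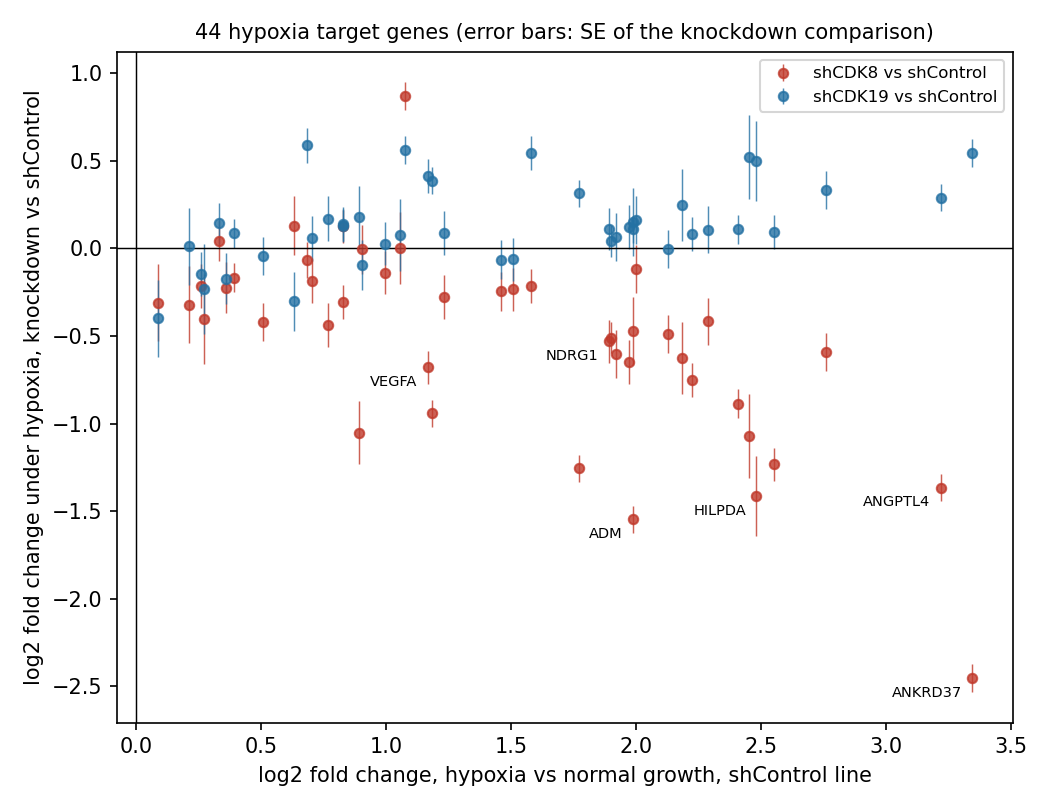
Log2 fold change of the 44 measured hypoxia targets in hypoxic against normally grown shControl cells (x axis) and in each knockdown line against shControl cells under hypoxia (y axis, error bars SE). Both axes use the hypoxic shControl arrays, so chance values of those arrays tilt the points downward. In the shCDK8 line 39 of 44 lie below 0 and in the shCDK19 line 10 of 44.

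The shCDK19 line under hypoxia had 36 genes higher and 6 lower than shControl cells. VSNL1 (5.01 ± 0.12), EHF (4.95 ± 0.23), TGFB2 (3.19 ± 0.18), ADGRF1 (3.12 ± 0.15), the glutamate transporter SLC1A3 (3.05 ± 0.13) and the Notch coactivator MAML2 (2.91 ± 0.19) were highest. PXDN (-2.64 ± 0.15), NR5A2 (-1.82 ± 0.11) and the inhibitor of differentiation ID3 (-1.16 ± 0.074) were lowest. Several lists were called although none of their members passed over all genes. Genes of sterol and fatty acid synthesis had a median of 0.44 (0 of 26 passed by limma [14 higher], with 16 higher and 0 lower at an unadjusted p under 0.05; p = 1.03e-10, and p = 0.571 with an estimated correlation). INSIG1 was at 0.51 ± 0.072 (adjusted p = 0.11). Hypoxia targets had a median of 0.11, or 0.030 after quantile normalization (0 of 44 passed by limma [5 higher], with 9 higher and 0 lower at an unadjusted p under 0.05; p = 0.000104, and p = 0.571 with an estimated correlation). VEGFA was at 0.41 ± 0.097 (adjusted p = 0.217) and NDRG1 at 0.11 ± 0.12 (adjusted p = 0.682). ATF4 targets had a median of 0.084, which turned to -0.014 after quantile normalization (0 of 34 passed by limma [0], with 8 higher and 2 lower at an unadjusted p under 0.05; p = 0.00521, and p = 0.571 with an estimated correlation). S phase genes had a median of -0.30 (0 of 44 passed by limma [11 lower], with 0 higher and 16 lower at an unadjusted p under 0.05; p = 1.03e-06, and p = 0.571 with an estimated correlation). Endothelial markers had one of -0.23 (0 of 10 passed by limma [1 lower], with 0 higher and 1 lower at an unadjusted p under 0.05; p = 0.0317, and p = 0.589 with an estimated correlation).
None of these 10 list calls held with an estimated correlation, by which 0 lists had even an unadjusted p under 0.05. The count of 42 genes was 4320 without shControl replicate 2, 2252 higher and 2068 lower, and 0 by limma without either shCDK19 array, where 1278 and 903 genes had an unadjusted p under 0.05. Between the knockdown lines under hypoxia, 1337 genes were higher and 936 lower in shCDK8 cells. Hypoxia targets were lower in shCDK8 than in shCDK19 cells (20 of 44 were lower [27 lower and 1 higher]; p = 1.05e-12, and p = 0.338 with an estimated correlation), with VEGFA at -1.09 ± 0.097 (adjusted p = 0.00884) and NDRG1 at -0.64 ± 0.12 (adjusted p = 0.037). Sterol and fatty acid genes were lower too (19 of 26 were lower [22 lower and 1 higher]; p = 2.64e-15, and p = 0.481 with an estimated correlation). This direct count of 2273 was 6, 0, 1 and 1 without shCDK8 replicates 1 and 2 and shCDK19 replicates 1 and 2 in turn. The limma fit that gave 0 had 3033 genes at an unadjusted p under 0.05.

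**Figure D3:**
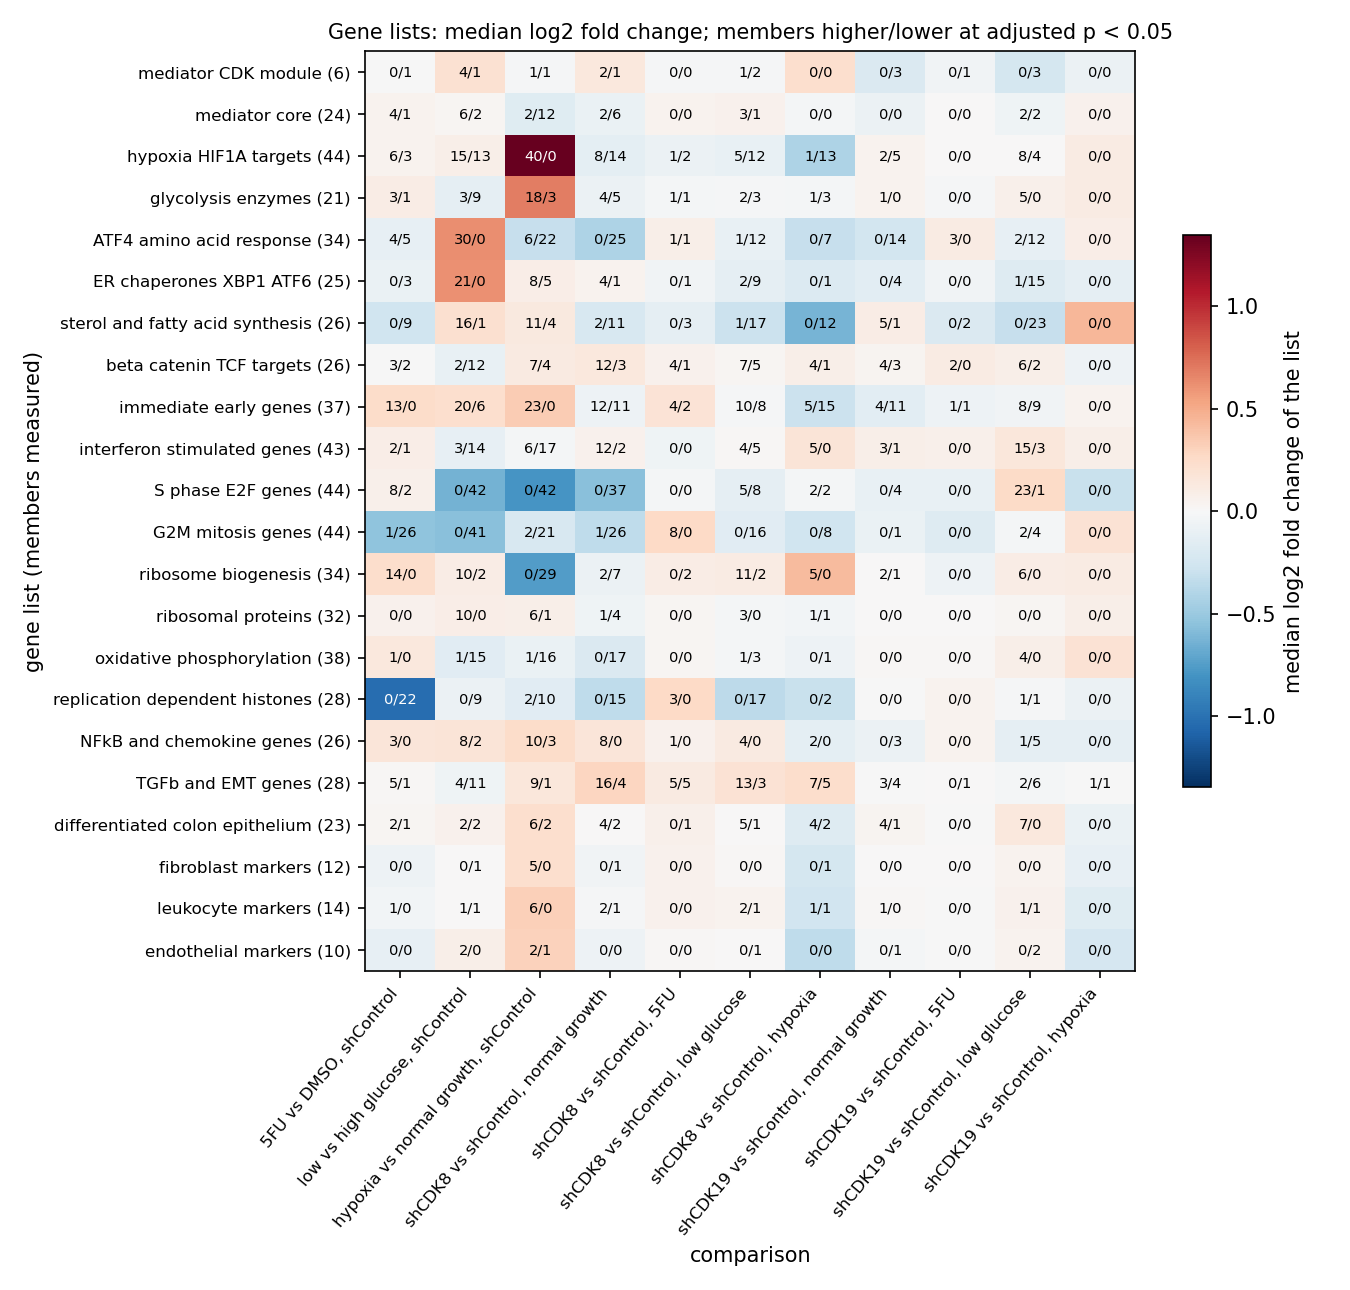
Median log2 fold change of each gene list reported (rows, with the number of measured members) in the 3 stress comparisons and the 8 knockdown comparisons (columns). Numbers in the cells are members higher and lower at an adjusted p under 0.05 over all genes, as in 40 higher and 0 lower for hypoxia targets in hypoxic shControl cells.

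Genes raised at least 2-fold by each stress in shControl cells were then followed in the knockdown lines under the same stress. These genes were chosen on the stressed shControl arrays that also serve as baseline, which pulls their median below 0 with no effect. The range of 100 simulated data sets without an effect is given. The 110 genes higher in hypoxic shControl cells had a median of -0.65 in the shCDK8 line (simulated -0.073 to -0.0048), where 50 were lower and 3 higher. Without shControl replicates 1 and 2 in turn, which also changes the genes chosen, 92 and 131 were lower. Without either shCDK8 array 0 passed by limma (68 and 64 were lower at an unadjusted p under 0.05). Their median was 0.11 in the shCDK19 line (simulated -0.076 to -0.0087). Without shControl hypoxia replicate 1 or 2 the shCDK19 median was -0.011 or -0.18. The 62 genes raised by low glucose had a median of -0.11 in the shCDK8 line (simulated -0.032 to 0.012) and -0.29 in the shCDK19 line (simulated -0.039 to 0.022), where 28 and 39 were lower and 11 and 9 higher. The 120 genes raised by 5-fluorouracil had a median of -0.094 in the shCDK8 line (simulated -0.052 to -0.0044), where 13 were lower and 4 higher. Without shControl replicates 1 and 2 and shCDK8 replicates 1 and 2 in turn, again with other genes chosen, 2, 3, 5 and 4 were lower. In the shCDK19 line their median was 0.076 (simulated -0.052 to 0.0050), and without 1 of shControl replicates 1 and 2 it was 0.19 or 0.049. The simulation draws noise gene by gene, without deviations shared by an array's genes, so small medians outside its range may be chance. With no fold minimum the shCDK19 medians turned to -0.042 (simulated -0.026 to -0.015) after 5-fluorouracil and -0.18 (simulated -0.052 to -0.039) under hypoxia. The others moved towards 0, for shCDK8 to -0.30 (simulated -0.053 to -0.041) under hypoxia, -0.033 (simulated -0.027 to -0.014) after 5-fluorouracil and -0.056 (simulated -0.019 to -0.013) in low glucose, and for shCDK19 to -0.082 (simulated -0.020 to -0.013) in low glucose.
To ask whether a knockdown acted differently under stress, its effect in each stress was compared with its effect in normal growth across all 35 arrays. Normal growth was a separate experiment, so stress and experiment cannot be told apart in these differences. The 3 differences of a line share its normal growth arrays, so agreement between them is partly built in. For shCDK8, 1151 genes had a higher and 1035 a lower effect under 5-fluorouracil, 1431 and 931 in low glucose and 1667 and 451 under hypoxia. These counts rest on an estimate of the spread shared by all 35 arrays. In a fit of only the groups compared, 168 genes passed under hypoxia in place of 2118. Under 5-fluorouracil the S phase genes (31 of 44 were higher [35]; adjusted p = 1.18e-21) and ATF4 targets (21 of 34 were higher [23]; adjusted p = 8.79e-19) had higher effects. So had histones (15 of 28 were higher [19]; adjusted p = 4.74e-16) and mitosis genes (27 of 44 were higher [40]; p = 1.03e-24, and p = 0.053 with an estimated correlation). CHAC1 (2.24 ± 0.19) and LYZ (-5.31 ± 0.20) had the extreme differences. In low glucose the S phase genes had a higher effect (27 of 44 were higher [34]; p = 3.46e-20, and p = 0.0941 with an estimated correlation). TM4SF1 (3.04 ± 0.14) and LYZ (-4.15 ± 0.18) were the extreme genes. Against shControl cells in low glucose, the median of the S phase genes in the shCDK8 line was -0.12. It was -0.031 under 5-fluorouracil and -0.56 in normal growth. The higher effects of the S phase genes in these 2 stresses were thus a smaller lowering than in normal growth, not a median above shControl cells. Under hypoxia, hypoxia targets had a lower effect (15 of 44 were lower [20 lower and 1 higher]; p = 6.82e-11, and p = 0.0505 with an estimated correlation). Sterol genes had a lower one too (14 of 26 were lower [17 lower and 1 higher]; p = 4.76e-13, and p = 0.0768 with an estimated correlation), and ribosome biogenesis genes a higher one (24 of 34 were higher [29]; p = 8.30e-19, and p = 0.0505 with an estimated correlation). INSIG1 (-2.30 ± 0.12) and ANKRD37 (-2.25 ± 0.16) differed most, NDRG1 had -0.57 ± 0.14 (adjusted p = 0.00816) and VEGFA -0.27 ± 0.096 (adjusted p = 0.0688). Leukocyte markers had a median difference of -0.24 there (1 of 14 was lower [1]; p = 0.00587, and p = 0.315 with an estimated correlation). The hypoxia count of 2118 was 1092, 6947 and 1121 without shControl replicates 1 and 2 and shCDK8 replicate 1 of that experiment. Its split was 953 higher and 886 lower with the interquartile range as a covariate, 647 higher and 497 lower without the 2 arrays that stood apart and 3999 higher and 2948 lower without hypoxic shControl replicate 2.
For shCDK19 the differences from normal growth were 402 higher and 334 lower genes under 5-fluorouracil, 182 and 147 in low glucose and 280 and 103 under hypoxia. With each array's median subtracted, the first and the last split were 153 higher and 201 lower and 95 higher and 17 lower, and with quantile normalization the last was 266 higher and 249 lower. In a fit of only the groups compared, 11 genes passed under hypoxia in place of 383, and 1190 under 5-fluorouracil in place of 736. ATF4 targets had a higher effect under 5-fluorouracil (18 of 34 were higher [23 higher and 1 lower]; adjusted p = 2.97e-25), in low glucose (7 of 34 were higher [8]; adjusted p = 9.18e-09) and under hypoxia (13 of 34 were higher [21]; adjusted p = 1.11e-19) than in normal growth, where their median was -0.25. Against shControl cells within low glucose their median was -0.11. Genes of sterol and fatty acid synthesis had a lower effect under 5-fluorouracil (12 of 26 were lower [15]; p = 9.28e-15, and p = 0.121 with an estimated correlation). They also had one in low glucose (13 of 26 were lower [22]; adjusted p = 3.68e-34). S phase genes had a higher effect in low glucose (19 of 44 were higher [28]; adjusted p = 3.68e-34). Under 5-fluorouracil CDKN1A differed by 0.83 ± 0.099 (adjusted p = 6.41e-06). PRKAA2 (3.91 ± 0.22) and DPP4 (-3.38 ± 0.21) were the extreme genes under 5-fluorouracil, LCN2 (2.04 ± 0.19) and UTS2B (-2.43 ± 0.21) in low glucose. Under hypoxia they were TSC22D3, a glucocorticoid-induced leucine zipper gene (2.08 ± 0.15), and FGF9 (-1.87 ± 0.21).
The count of 736 for 5-fluorouracil was 473 or 445 without shCDK19 replicate 1 or 2. For hypoxia the count of 383 was 198 and 4567 without hypoxic shControl replicates 1 and 2, 80 without hypoxic shCDK19 replicate 2. It was 228, 253 and 198 without normally grown shControl replicates 1 to 3, and 214 and 176 without normally grown shCDK19 replicates 2 and 3.
Genes that passed in the same direction in all 4 experiments numbered 115 higher and 88 lower in the shCDK8 line, where independent calls would give 0.193 and 0.121. In the shCDK19 line they numbered 17 higher and 1 lower. Of these, 12 were shared by both lines, 11 higher and 1 lower. These numbers rested on the experiments with 2 arrays per group: without hypoxic shCDK8 replicate 1 or 2, 4 or 2 of the 203 shCDK8 genes passed in all 4. None of the lower ones did by limma (232 or 224 genes were lower at an unadjusted p under 0.05 in all 4). Without either hypoxic shCDK19 array 0 of the 18 and 0 of the 12 passed by limma, and with the replicate block 80 of the 203, 1 of the 18 and 1 of the 12 did. Without 1 of the 6 arrays of 5-fluorouracil-treated cells 62 to 104, 3 to 7 and 2 to 4 of them passed. With any 1 of the arrays compared left out, all 203 and all 18 kept their direction in all 4. This is largely built in, since the remaining arrays also served to choose these genes. VSNL1 was higher by 4.19 to 5.34 in the shCDK8 and by 4.47 to 5.80 in the shCDK19 line, and EHF by 2.74 to 4.69 and 3.48 to 4.95. The shared gene that was lower, NR5A2, a nuclear receptor, fell by 1.55 to 2.58 on the log2 scale in the shCDK19 line. Both lines share an experiment's shControl arrays, which alone makes fold changes correlate. Across genes, which are not independent replicates, the correlation of the knockdown effects was 0.316 in normal growth, 0.372 under 5-fluorouracil, 0.406 in low glucose and 0.328 under hypoxia, against 0.50 in simulated unchanged groups in each. The covariance excess over simulation was 0.0170, 0.0111, 0.0248 and 0.0263, the last perhaps from shControl noise. In normal growth 360 genes were higher and 269 lower in both lines, and 215 were called in opposite directions. The numbers were 53, 19 and 5 under 5-fluorouracil, 730, 727 and 316 in low glucose, and 24, 2 and 4 under hypoxia. Of all genes, 58.7%, 59.9%, 61.6% and 66.0% had the same sign in both lines in these 4 experiments, against 66.7% in simulated unchanged groups of the first.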

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

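The tests that weigh explanations in this part were chosen after the results were seen, except the one for a mislabelled array, and the tests of differences between stress and normal growth were planned before.
The 2 arrays that stood apart from their groups were shControl hypoxia replicate 1 and shCDK8 normal growth replicate 1. They lay at one end of a component that held 47.5% of the variance within groups (the next held 5.56%), and with 2 hypoxic shControl arrays the odd one was judged from its interquartile range of 3.24 log2 units, the lowest of the 35. A compressed signal range is a candidate explanation for the shCDK8 array, in which the deviation ran against the gene's mean level across genes (r = -0.391), while the hypoxic array was picked by its range, so that its r of -0.399 decides nothing there. RNA of other cells was neither excluded nor borne out, although the samples were described as HCT116 cells. The 36 markers of fibroblasts, leukocytes and endothelium lay at the 97.8th percentile of 10000 random lists of like mean level. This test took the deviation averaged over both arrays, so it does not speak for either array alone. Only 5 of the markers lie above the median level of all genes. The leukocyte gene PTPRC was at or near the floor in both groups. A wrong label was neither excluded nor borne out by a highest slope on another group's difference of 0.452 for the shControl array and 0.309 for the shCDK8 array, and the design names no biological explanation for single arrays.
Hypoxia targets were lower in hypoxic shCDK8 than in hypoxic shControl cells, by a median of -0.417. The shControl array that stood apart does not account for this, since the median without it was -0.533, and -0.552 and -0.527 for the 2 shCDK8 arrays taken singly. A difference already present in normal growth is not excluded. The median difference of effects, hypoxia minus normal growth, was -0.297, and its call did not hold with an estimated correlation. It lay between -0.494 and -0.214 over 36 overlapping sets of arrays left out. The median of these targets was -0.13 in normal growth (camera adjusted p = 0.0881). It was -0.078 under 5-fluorouracil (p = 0.0772) and -0.10 in low glucose (p = 0.0227, a call that did not hold with an estimated correlation). A weaker response to hypoxia of the shCDK8 culture as a whole may be involved: the 316 genes at least 2-fold lower in hypoxic shControl cells had a median of 0.707 in shCDK8 against shCDK19 cells (0.650 to 0.766 with arrays left out), and the 110 genes at least 2-fold higher one of -0.836. The lower hypoxia targets may reflect CDK8 or a culture difference such as oxygen or density. With 1 line and 2 arrays per group these cannot be told apart, so a role of CDK8 remains a hypothesis.
Both knockdown lines shared 12 genes past the threshold in all 4 experiments, namely VSNL1, EHF, FGF9, KIAA0040, ANO1, DPYSL3, DCLK1, EMP1, KHDRBS3, INPP4B and ZNF827, which were higher, and NR5A2, which was lower. By limma 0 of the 12 passed without either hypoxic shCDK19 array, where all 12 had an unadjusted p under 0.05 in all 4. Chance values of the shared shControl arrays are argued against by an expected number of 5.48e-05 genes if experiments were independent. A peculiarity of the single shControl line, in which these genes could differ from both other lines, cannot be told apart from a shared effect of both hairpins, because only 1 control line was used, so that a function shared by CDK8 and CDK19 is one of 2 open hypotheses. Of the 12 genes, 0 differed between the knockdown lines by more than their smaller change against shControl in over 2 experiments, by limma, which either reading allows.
The tests of the difference between stress and normal growth also marked single results. For shCDK8, 2186 genes differed under 5-fluorouracil, with CHAC1 at 2.24 ± 0.19, SPTSSB at 2.20 ± 0.16, LYZ at -5.31 ± 0.20 and TNFSF18 at -4.27 ± 0.19. In low glucose 2362 differed, with TM4SF1 at 3.04 ± 0.14, CYB5A at 2.64 ± 0.18, LYZ at -4.15 ± 0.18 and SUSD2 at -3.19 ± 0.12. Under hypoxia 2118 differed, with SLC10A5 at 1.79 ± 0.36, CHRNA5 at 1.55 ± 0.21, INSIG1 at -2.30 ± 0.12 and ANKRD37 at -2.25 ± 0.16. For shCDK19 the number was 736 under 5-fluorouracil, with PRKAA2 at 3.91 ± 0.22, PXDN at 2.30 ± 0.17, DPP4 at -3.38 ± 0.21 and CAPN6 at -3.14 ± 0.17. It was 329 in low glucose, with LCN2 at 2.04 ± 0.19, SLPI at 1.98 ± 0.17, UTS2B at -2.43 ± 0.21 and INSIG1 at -1.40 ± 0.10, and 383 under hypoxia, with TSC22D3 at 2.08 ± 0.15, CHAC1 at 1.97 ± 0.19, FGF9 at -1.87 ± 0.21 and TNS4 at -1.01 ± 0.11. Among the 13163 transcript clusters without a single gene symbol, which apart from that of CDK8 and ADRA1B enter no comparison above, 6 were higher in shCDK8 than in shControl cells in all 4 experiments, which was not tested with arrays left out.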

How the results depend on the processing

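The main counts stand in the report, and each alternative changed 1 choice, except that the unadjusted analysis of variance dropped the moderation and the adjustment together. Chosen after seeing the data were leaving out genes with 1 value on all arrays of a fit, leaving out the 2 arrays that stood apart from their groups, taking each array's interquartile range as a covariate, and the counts with arrays left out or a block of genes that passed in all 4 experiments, and the other alternatives were chosen before. Of 4030 values of named genes under the alternatives, 3811 kept direction and side of the threshold, 177 fell short of it, 42 came past it and 0 turned direction. Of 1001 values of gene lists, judged by the direction of camera's test, the numbers were 759, 213, 24 and 5. The counts below are numbers of genes that moved by over 1.5 times. The majority, of higher or of lower genes, turned under 6 of 18 alternatives for shCDK19 and 4 of 18 for the direct comparison in normal growth, and under 5 of 15, 1 of 15 and 1 of 15 for shCDK8, shCDK19 and the direct comparison under 5-fluorouracil. It turned under 1 of 17 for shCDK19 in low glucose, 2 of 16 for shCDK8 under hypoxia and 2 of 19 for hypoxia in shControl cells. For the differences it turned under 5 of 22 for shCDK8 under 5-fluorouracil, and for shCDK19 under 5 of 22, 5 of 24 and 1 of 22 under 5-fluorouracil, in low glucose and under hypoxia. It did not turn for the other results. Signal over background is not given in the sources used here, so only the floor bounds what dim genes can show.
A second quantile normalization called 271 for shCDK19 under 5-fluorouracil. Subtracting array medians called 781 for shCDK19 in normal growth and 122 for shCDK19 under hypoxia, and for the differences of the shCDK19 effect 354 under 5-fluorouracil, 146 in low glucose and 112 under hypoxia. Without the 40% dimmest genes there were 1002 for shCDK8 under 5-fluorouracil, 473 for shCDK19 under 5-fluorouracil, 1482 for the direct comparison there and 160 for shCDK19 under hypoxia. Testing every cluster called 2 for shCDK19 under hypoxia. In 1 fit of all 35 arrays there were 1713 for shCDK8 under 5-fluorouracil, 1067 for shCDK19 under 5-fluorouracil, 2221 for the direct comparison there, 6392 for shCDK8 under hypoxia, 2641 for shCDK19 under hypoxia, 5925 for the direct comparison under hypoxia and 3526 for 5-fluorouracil against DMSO. With only the arrays of the groups compared, 3242 genes passed for hypoxia against normal growth, 168 for the shCDK8 difference under hypoxia and 1190 and 11 for the shCDK19 differences under 5-fluorouracil and hypoxia. With the trend and robust options of eBayes there were 1192 for shCDK8 under 5-fluorouracil, 577 for shCDK19 under 5-fluorouracil, 1649 for the direct comparison there and 212 for shCDK19 under hypoxia. The unmoderated analysis of variance called, after adjustment, 238 for shCDK8 under 5-fluorouracil, 20 for shCDK19 under 5-fluorouracil, 287 for the direct comparison there, 334 for shCDK8 under hypoxia, 3 for shCDK19 under hypoxia, 765 for the direct comparison under hypoxia and 849 for 5-fluorouracil against DMSO. At an unadjusted p under 0.05 it gave 3251 for shCDK19 in normal growth, 2680 for shCDK8 under 5-fluorouracil, 2130 for shCDK19 under 5-fluorouracil, 3190 for the direct comparison there and 5508 for shCDK19 in low glucose. It also gave 3902 for shCDK8 under hypoxia, 2163 for shCDK19 under hypoxia, 4268 for the direct comparison under hypoxia and 4242 for 5-fluorouracil against DMSO. For the shCDK8 differences under 5-fluorouracil, in low glucose and under hypoxia the numbers were 3947, 4178 and 4809, and 2391, 1911 and 2921 for those of shCDK19. Such counts include genes past the threshold by chance. Leaving out constant genes called 283 for shCDK19 under 5-fluorouracil and 91 for shCDK19 under hypoxia. Without the 2 arrays that stood apart there were 2531 for shCDK19 in normal growth, 7349 for the direct comparison in normal growth, 4914 for the direct comparison under hypoxia and 5064 for hypoxia against normal growth. The numbers were 1144 for the shCDK8 difference under hypoxia and 1212 and 603 for the shCDK19 differences under 5-fluorouracil and in low glucose. With the interquartile range as a covariate there were 7701 for shCDK8 in normal growth, 3239 for shCDK19 in normal growth, 8019 for the direct comparison in normal growth, 1506 for shCDK8 under 5-fluorouracil, 671 for shCDK19 under 5-fluorouracil and 2249 for the direct comparison there. The numbers were 2196 for shCDK8 under hypoxia, 142 for shCDK19 under hypoxia, 5587 for the direct comparison under hypoxia, 3463 for 5-fluorouracil against DMSO and 5214 for hypoxia against normal growth. They were 3713 and 4021 for the shCDK8 differences under 5-fluorouracil and in low glucose, and 1639, 1013 and 661 for the 3 shCDK19 differences. The splits with this covariate were 325 higher and 346 lower for shCDK19 and 1208 higher and 1041 lower for the direct comparison under 5-fluorouracil, and 101 higher and 41 lower for shCDK19 and 312 higher and 349 lower for its difference under hypoxia.
The numbers of the replicates were not taken to pair the arrays: the correlation of deviations between arrays with the same number in different groups lay between -0.62 and 0.367 in normal growth (over 0.1 in 2 of 9 pairs), -0.305 and 0.389 in the 5FU experiment (over 0.1 in 3 of 6 pairs), -0.17 and 0.311 in the glucose experiment (over 0.1 in 2 of 18 pairs) and -0.496 and 0.41 in the hypoxia experiment (over 0.1 in 1 of 3 pairs). With 2 arrays per group the deviations mirror each other, so each pair of groups in the 5FU and hypoxia experiments gave 1 value, which cannot show whether the numbers pair the arrays. With the replicate number as a replicate block there were 781 for shCDK19 in normal growth, 355 for shCDK8 under 5-fluorouracil, 53 for shCDK19 under 5-fluorouracil and 479 for the direct comparison there. It gave 312 for shCDK8 under hypoxia, 1 for shCDK19 under hypoxia, 764 for the direct comparison under hypoxia and 5002 for hypoxia against normal growth. The other counts moved by less than 1.5 times.
With an estimated correlation the number of lists called by camera went, for shCDK8 and shCDK19 in turn, from 12 and 11 to 0 and 0 in normal growth (5 and 3 at an unadjusted p under 0.05), from 5 and 8 to 0 and 0 under 5-fluorouracil (1 and 1), from 10 and 12 to 2 and 2 in low glucose and from 10 and 10 to 0 and 0 under hypoxia (2 and 0). It went from 10 to 0 for 5-fluorouracil (4 at an unadjusted p under 0.05), from 12 to 4 for low glucose and from 14 to 3 for hypoxia in shControl cells. For the differences from normal growth under 5-fluorouracil, in low glucose and under hypoxia it went from 14, 12 and 8 to 7, 0 and 0 with shCDK8 (7 at an unadjusted p under 0.05 for hypoxia and 6 for low glucose) and from 5, 6 and 14 to 2, 3 and 1 with shCDK19. Without the 40% dimmest genes 6 lists were called for shCDK8 in low glucose, 6 for shCDK19 under hypoxia and 7 for its difference there. Without the 2 arrays that stood apart 16 lists were called for shCDK8 and 5 for shCDK19 under hypoxia, 9 for hypoxia in shControl cells and 6 for the shCDK19 difference.
Without those 2 arrays camera's test turned direction for 5 list results, of which 4 were called in the main test. Under hypoxia the mitosis median went from 0.192 to -0.0145 and the ribosome biogenesis median from 0.116 to -0.0292 for shCDK19. The mitosis median for hypoxia in shControl cells went from -0.211 to -0.0155 and the ribosome biogenesis median of the shCDK19 difference from 0.147 to 0.00528, so neither median changed sign. The mitosis median of the shCDK8 difference, not called in the main test (adjusted p = 0.819), went from 0.0759 to -0.227 (adjusted p = 1.91e-10). With no fold minimum the median of stress-induced genes with shCDK19 turned to -0.042 under 5-fluorouracil and -0.18 under hypoxia, and moved towards 0 to -0.082 in low glucose. With shCDK8 they moved to -0.033, -0.056 and -0.30 under 5-fluorouracil, in low glucose and under hypoxia. Leaving out 1 array at a time gave, for shCDK8, shCDK19 and the direct comparison, in normal growth 3190 to 6713, 662 to 814 and 3587 to 7349 genes, under 5-fluorouracil 88 to 158, 5 to 9 and 40 to 158, in low glucose 3227 to 3667, 2700 to 3655 and 3914 to 4918, and under hypoxia 2 to 8548, 0 to 4320 and 0 to 6. For 5-fluorouracil, low glucose and hypoxia in shControl cells it gave 225 to 2987, 4809 to 5100 and 4549 to 12096, for the 3 shCDK8 differences 1567 to 2304, 1879 to 2362 and 1092 to 6947 and for the 3 of shCDK19 445 to 619, 226 to 310 and 80 to 4567. Where this left a group with 1 array, that array was assumed to vary like the others. The medians of stress-induced genes lay, for shCDK8 and shCDK19, between -0.14 and -0.10 and between 0.049 and 0.19 under 5-fluorouracil, -0.14 and -0.11 and between -0.32 and -0.25 in low glucose, and -0.90 and -0.63 and between -0.18 and 0.19 under hypoxia. The cause was not tested.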

Other observations

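The ZNF test and the choice of genes in this part were made after results were seen, and the counts of splits were planned before.
Several other genes, chosen here after their values were seen, passed in the shCDK8 line in all 4 experiments. Compared with shControl cells, the log2 fold change of SLCO3A1, an organic anion transporter, lay between 2.43 and 3.03 and that of NRG1, a ligand of ERBB receptors, between 1.39 and 1.99. That of the Notch ligand JAG1 lay between 1.10 and 1.92, that of EFNB2, an ephrin, between 1.02 and 2.17 and that of SLIT2, a guidance ligand, between 1.17 and 1.85. The nuclear receptor PPARG was higher by 1.18 to 2.54 and the epithelial-mesenchymal regulator ZEB1 by 0.38 to 1.51. In the shCDK19 line the transcription factor genes HOXB8 (1.21 to 1.73) and NR2F1 (0.86 to 1.27) were higher in all 4. These calls rested on the hypoxia arrays: without shCDK8 replicate 1 or 2, 4 or 2 of the 203 genes of the shCDK8 line passed in all 4, and without either shCDK19 array 0 of the 18 of the shCDK19 line by limma, where all 18 had an unadjusted p under 0.05.
The hypothesis that zinc finger genes named ZNF are over-represented among the 88 genes lower in the shCDK8 line in all 4 experiments was not borne out: 1 of the 88 carried such a name, against 494 of the 18404 genes tested (two-sided Fisher's exact test, p = 0.734, odds ratio 0.416 with a 95% interval from 0.0104 to 2.39).
Other splits of the arrays were counted where each group had 3 arrays. For the 7 comparisons of 2 groups the real split gave 4579, 1301 and 4805 genes in normal growth (shCDK8, shCDK19 and direct), 4107, 3671 and 4778 in low glucose and 5738 for low against high glucose. In each case 1 of 10 splits, the real one, gave as many genes, and the highest other split gave 2 genes in the direct low glucose comparison and 0 by limma in the others, but 10 splits are too few for a share under 0.05. For the differences between low glucose and normal growth, 6 of 100 splits gave as many as the 2362 genes for shCDK8 (highest other 5390) and 10 of 100 as many as the 329 genes for shCDK19 (highest other 3643), so chance could not be excluded by this count. The 5 and 9 other splits exchanged most arrays of the 2 groups within 1 experiment, which keeps much of the contrast between the lines, and points to that structure of the samples. Among the 54 drawn splits without such an exchange the highest counts were 1687 and 266.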
